A study of Homo sapiens with 42 samples.

How the data were processed

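RNA was sequenced from extracellular vesicles, membrane-bound particles released by cells, isolated from ventricular cerebrospinal fluid (CSF) of 42 patients diagnosed with normal pressure hydrocephalus. Per the labels' protocols, the fluid was cleared by low-speed centrifugation and frozen, vesicles were pelleted by ultracentrifugation, and RNA was extracted with a kit that retains small RNA before a standard Illumina cDNA preparation. The labels name the molecule as polyA RNA. The values used are read counts per gene, deposited by the authors as 1 table of whole numbers with a column per library. The submitters' processing notes name Trim Galore 0.5.0, FastQC 0.11.5, HISAT2 2.1.0, SAMtools 1.9, StringTie 1.3.4, DESeq2 1.34.0 and the build hg38, without their order or role. The annotation, the counting settings, the use of strand, the treatment of reads with several mapping places and the removal of duplicate reads are not given in the sources used here. Genes with near-identical copies (RN7SL1 and RN7SL2, the 5S and 5.8S rRNA genes, HBA1 and HBA2, HSPA1A and HSPA1B, mitochondrial genes and their nuclear pseudogenes) therefore have an uncertain split of reads, as do overlapping and antisense genes.

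The labels put all 42 libraries in 1 group and give no outcome of shunt surgery for any library, so the response named in the series title is not analysed here and no groups were compared. Libraries were treated as 42 replicates of 1 group. A chi-square test of the counts of each of 861 pairs of libraries, over genes with at least 10 counts in the pair, found none alike within sampling noise: the lowest ratio of chi-square to its degrees of freedom was 35.5. This would find a copied or resequenced library, and cannot tell whether 2 separately prepared libraries share a sample.

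The table holds 39395 named genes and 1 row without a gene name. That row took a median of 76.5% of each library's counts (range 52.8% to 83.4%) and was left out of library sizes and tests. Of the gene names, 38949 matched the gene name table and 36896 matched GENCODE release 29, from which coordinates on GRCh38 (hg38) and gene types were taken. RNA classes were built from gene symbols, GENCODE types and RefSeq biotypes; this grouping was defined after the data were examined.

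Depth is the sum of counts over named genes, with a median of 7292928 per library (range 764698 to 19692429). A count of 0 allows up to 3 counts, which is a median of 0.483 CPM (counts scaled to a common library size by the factors below; range 0.157 to 1.92). Small counts peaked at multiples of 3: over all genes and libraries, a count of 3 occurred 6266 times, 2 occurred 3295 times and 4 occurred 2893 times. A count of 1 is therefore not taken as 1 read, and limits and thinning are in counts. No molecular identifiers are named in the labels, so these limits cover counting error only. Library sizes were scaled by the trimmed mean of M-values (TMM) in edgeR 4.0.16 (R 4.3.3, limma 3.58.1) on the 7700 genes with at least 10 counts in at least 21 libraries, and the TMM factors ran from 0.469 to 2.20. CPM values are scaled in this way; log2 CPM used a prior count of 2.

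Variability between libraries was tested per gene with edgeR's quasi-likelihood fit with an intercept only. The F ratio sets a gene's quasi-dispersion against the trend of genes of like abundance, in a one-sided test for a ratio above 1 with Benjamini-Hochberg adjustment and a threshold of 0.05. On simulated counts for the same 7700 genes, this called 8 of 100 genes with a 2-fold raised dispersion, 48 of 100 with a 3-fold raised dispersion and 2 of 7500 unchanged genes.

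The 26 gene lists were fixed before the data were examined, and 1 of their 367 members had no row. A list with at least 3 members past the count filter was scored, which left 18. Coherence of a list is the mean Spearman correlation over pairs of its members, set against 10000 random lists of the same size, each drawn without repeats from the 200 genes nearest to each member in mean log2 CPM; its p is one-sided. A list score is the mean over members of z-scored log2 CPM. Scores were correlated over the 42 libraries for 153 pairs of lists, without shared members, and for 36 relations with log10 total count and with the number of detected genes. Pearson's r and Spearman's rho were tested two-sided with 100000 permutations and Benjamini-Hochberg adjustment within each family, and rho of each pair was set against 1000 pairs of random lists. The smallest p these permutations can give is 1e-05. Pearson's r was given again without the 2 libraries farthest from the median of the first measure. Principal components were taken from gene-centred log2 CPM. The window of 200 genes was chosen after the data were examined, because a narrower one could not fill lists as long as the ribosomal protein list. On shuffled data, coherence called 10 of 10 lists given a shared factor and 0 of 10 without, and 0 of 190 pairs of lists were called correlated. In the data as measured, random pairs of lists had a median rho of 0.524. The 0 of 190 therefore does not show how often unrelated lists pass in these libraries. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1 was used.

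After the correlations were seen, the choroid plexus and ependymal lists were joined into a lining score and the neuron, astrocyte, oligodendrocyte, precursor and microglia lists into a parenchyma score. The gap between these sets (mean rho within minus mean rho between) was set against 1000 sets of random lists, each split at its own best. Each gene was then fitted on both scores, in SD, with detected genes and log10 total count, by edgeR quasi-likelihood. The dispersion method of this fit was changed after the results of a first fit on the data had been seen. The first fit used edgeR's current method, and a self-test run afterwards on simulated counts of 7700 genes called 16 of 7500 unchanged genes, 11 of 100 genes given 1 log2 unit per SD and 17 of 100 given 1.5. The current and earlier methods of edgeR and limma-trend were compared on simulated counts, and the earlier method of edgeR was adopted, with 0, 4 and 7 calls. Counts of both fits are given. Cilia genes were also fitted on the choroid plexus score in place of the lining score.

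Totals with the unnamed row included showed 5 libraries at 67248162 counts or more and the other 37 at 46567655 or fewer. No label gives a sequencing batch. This split was treated as a possible one, found after the data were examined, and relations between scores were repeated in the 37 libraries; 5 libraries are too few for a value of their own.

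The text names the 25 genes with the highest median CPM, the 20 genes with the largest F ratio past the threshold and the 5 with the smallest, up to 4 members of each list with the highest median CPM and members that were not detected, and the 10 genes with the largest positive and negative loadings of components 1 and 2. Some genes that these rules pick are not reported here. XIST, TSIX, Y-linked genes, HLA class II genes, GSTM1, GSTT1 and UGT2B17 are not reported here because their level can identify a person's sex or genotype. The 10 most abundant nuclear protein-coding genes were added after their values were seen.

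Alternatives set before the data were examined were DESeq2 size factors (version 1.42.0, the setting that uses positive counts) and total counts in place of TMM, a prior count of 0.5, filters of at least 5 counts in at least 11 libraries, at least 10 counts in all libraries or none, DESeq2's dispersion outliers, thinning to the shallowest library, detection at 10 counts, genes scaled to unit variance, total count and detected genes regressed out, and the data without the 4 shallowest libraries. Added after the data were examined were the data without the 5 deepest libraries, without the library of highest neuron list level, without RN7SL2, HBA2 and HSPA1B, thinning in units of 3 counts, and the first fit on the lining and parenchyma scores.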

Results

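The study profiled RNA carried by extracellular vesicles of ventricular CSF, the fluid inside the brain's ventricles, in normal pressure hydrocephalus, a condition in which the ventricles enlarge and which is treated by a surgical shunt. There were 42 libraries in 1 group. The series title asks whether CSF transcripts foretell the response to shunt surgery, and since no label gives an outcome per library, that comparison is not analysed here. The values below describe which RNAs the vesicle fraction held and how they varied from library to library.

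Counts over named genes came to a median of 7292928 per library (range 764698 to 19692429). A median of 8791 genes had at least 1 count (range 2380 to 13028), and 8138 had at least 10 (range 2176 to 11293). Of 39395 named genes, 24730 had a count in at least 1 library, 371 in all 42, and 4952 in exactly 1 library. Deeper libraries held more genes (Spearman rho = 0.673, Pearson r = 0.698 on log10 total count, both permutation p = 1e-05, n = 42), with r = 0.628 without the 2 libraries farthest from the median depth and rho = 0.695 in the 37 libraries that are not the deepest 5. When all libraries were thinned to 764698 counts, the median number of detected genes was 8366.5 (range 2321 to 10739). The genes detected after thinning still followed the original total count (rho = 0.616), so the relation largely remained at equal depth. A median of 1.42% of a library's detected genes had a count of 1, though small counts peaked at multiples of 3 and a count is not taken as 1 read, and the median count of a detected gene was 70.5 (range 21 to 202).

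Structural RNAs made up most of the named counts, although the labels name the molecule as polyA RNA; how far the shares below describe a polyA fraction is uncertain. The 7SL RNA of the signal recognition particle, with its many genomic copies, took a median of 37.3% of named counts (range 11.7% to 55.4%). The mitochondrial rRNAs took 18.7% (range 1.32% to 60.7%), and 5S and 5.8S rRNA together took 16.1% (range 7.04% to 22.8%). Y RNAs, small cytoplasmic RNAs bound by the Ro protein, held 1.75% (range 0.541% to 4.57%). Nuclear protein-coding genes held 18.5% (range 10.0% to 36.9%), mitochondrial mRNAs 2.61% (range 0.0514% to 22.4%), long noncoding RNAs 0.453% and mitochondrial tRNAs 0.0718%. The 10 most abundant genes of a library took a median of 67.8% of its named counts (range 49.3% to 79.3%).

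**Figure D1:**
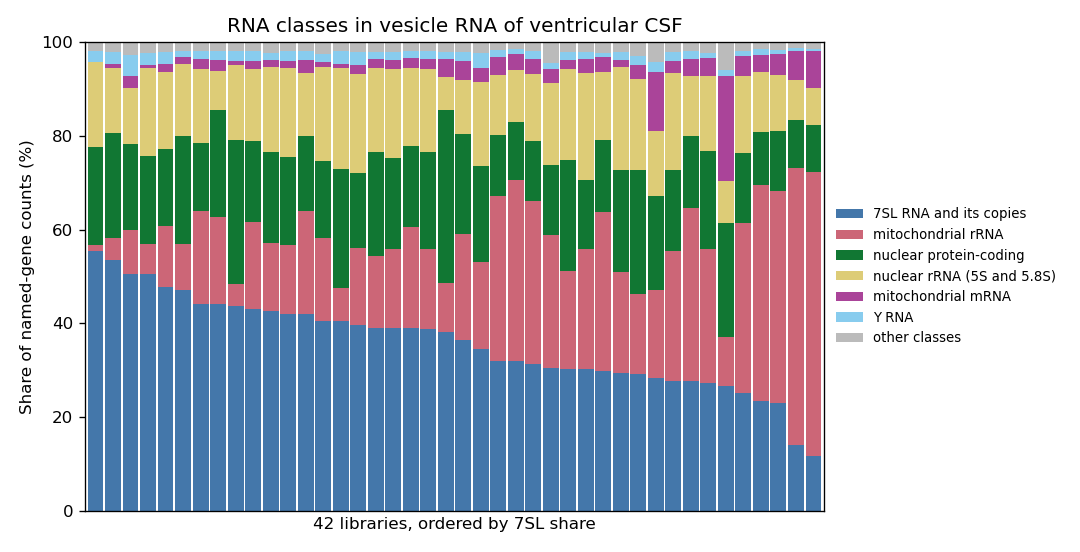
Share of named-gene counts (%) by RNA class in each of the 42 libraries, ordered from left to right by the 7SL share; each stacked bar is 1 library. The 7SL share falls from 55.4% to 11.7% across the plot, and mitochondrial rRNA ranges from 1.32% to 60.7%.

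Each of the 25 genes with the highest median CPM had counts in all 42 libraries. They comprised 13 rRNA genes, 4 genes of 7SL RNA, 3 Y RNA genes, 2 mitochondrial rRNAs, 2 mitochondrial mRNAs and 1 nuclear mRNA. RN7SL1 (chromosome 14, 49586580 to 49586878) had a median of 165583 CPM (range 47236 to 280211) and RN7SL2 (chromosome 14, 49862550 to 49862849) had 163749 CPM; the split of reads between these near-identical genes is uncertain. The copies RN7SL4P and RN7SL5P stood at 18359 and 13170 CPM (medians). The mitochondrial rRNAs MT-RNR2 (positions 1671 to 3229 of chromosome M) and MT-RNR1 (648 to 1601) had medians of 115189 and 67524 CPM. Also in this set were 5_8S_rRNA, RNA5-8SN1 to RNA5-8SN5 with medians between 10375 and 24204 CPM, RNA5S1 to RNA5S7 with medians between 3100 and 21540.1 CPM, and RNY1, RNY3 and Y_RNA with 8014, 3017 and 3408 CPM.

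The most abundant nuclear mRNA was MBP, which encodes myelin basic protein of oligodendrocytes (chromosome 18, 76978827 to 77133683), at a median of 5669 CPM (range 208 to 23022). The mitochondrial mRNAs MT-CO1 and MT-ND4 followed at 4724 and 3319 CPM. Next among nuclear mRNAs were the translation factor EEF1A1 (2782 CPM), ERICH3 (chromosome 1, 74568111 to 74673738; 2311 CPM, range 283 to 16777), and TTR, the thyroid hormone carrier transthyretin made in the choroid plexus (chromosome 18, 31557010 to 31599021; 1474 CPM, range 368 to 3396). MTURN (885 CPM, with a count in 41 libraries), TPT1 (676 CPM), HIPK2 (612 CPM), the ferritin chains FTH1 (553 CPM) and FTL (489.6 CPM), and RPL3 (537 CPM) completed the first 10.

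The gene lists of brain and ventricle cell types were all represented, and their summed levels differed widely. Oligodendrocyte genes had the highest summed level of the cell type lists, with a median of 6439.5 CPM (range 275 to 24890.4), of which MBP was 88.7%. ERMN (163 CPM) and MOBP (155 CPM), also of myelin-forming cells, came next. Choroid plexus epithelium genes summed to 2174 CPM (range 514 to 4300.04), 72.2% of it TTR, followed by CLIC6 (134 CPM), SLC13A4 (77.7 CPM) and the prolactin receptor PRLR (64.0 CPM). The oligodendrocyte sum exceeded the choroid plexus sum in 36 of 42 libraries, with a median ratio of 3.11. Astrocyte genes summed to 712 CPM (range 241 to 1441), led by the intermediate filament GFAP (226 CPM), NDRG2 (144 CPM), S100B (102 CPM) and the water channel AQP4 (45.1 CPM). Genes of ependymal cells and motile cilia summed to 267 CPM (range 37.5 to 678), with the ciliary transcription factor FOXJ1 at 44.6 CPM, DNAH11 at 38.7 CPM, PIFO at 26.2 CPM and CFAP126 at 24.3 CPM. The choroid plexus sum was above the ependymal sum in 42 of 42 libraries, by a median ratio of 8.10.

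Neuron genes summed to 178 CPM (range 30.8 to 933), with STMN1 at 31.2 CPM, MAP2 at 30.7 CPM, ENO2 at 12.8 CPM and SNAP25 at 12.2 CPM. Of 18 neuron genes, 15 had a count in at least 21 libraries. RBFOX3, SYN1 and GAD1, named after their values were seen, had a count in 10, 11 and 17. Genes of oligodendrocyte precursors summed to 117 CPM (range 19.02 to 349), with VCAN at 41.3 CPM, OLIG1 at 13.4 CPM, TNR at 12.8 CPM and PTPRZ1 at 10.2 CPM. Microglia and macrophage genes were low, at a sum of 40.2 CPM (range 0 to 104): CX3CR1 had a count in 26 libraries, C1QB in 26, P2RY12 in 29 and AIF1 in 22. Mural and fibroblast genes summed to 103 CPM (range 8.30 to 451), led by PTGDS (48.1 CPM), RGS5 (11.7 CPM), COL1A2 (9.33 CPM) and COL3A1 (6.61 CPM). Endothelial genes summed to 11.0 CPM (range 0 to 61.7); CLDN5 had a count in 29 libraries, FLT1 in 18, PECAM1 in 16 and VWF in 11, and ESAM in none.

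Genes of lymphocytes, neutrophils and platelets had low median sums, and erythroid genes were higher. Erythroid genes had a count in 41 of 42 libraries and summed to 45.5 CPM (range 0 to 490.1), with the globins HBA2 and HBA1 at 5.13 and 3.75 CPM and BPGM at 3.47 CPM. HBA1 and HBA2 each had a count in 27 libraries, HBB in 20, and HBD and ALAS2 in 1 each. A count for the list therefore need not mean globin RNA in that library. T and NK cell genes had a median sum of 3.14 CPM (range 0 to 68.6): CD3E and IL7R had a count in 13 libraries, CD3G in 7, CD2 in 7 and CD3D in 4. B and plasma cell genes had a median sum of 0.789 CPM; 1 library reached 585 CPM and the next highest 27.1 CPM. Among them MS4A1 and CD79B each had a count in 6 libraries and CD79A in 1, and IGKC and JCHAIN in 9 and 7. Neutrophil genes had a median of 0 (highest 101 CPM): S100A9 had a count in 5 libraries, FCGR3B in 2, and S100A8 and S100A12 in 1 each, while MNDA had a count in 12 and CSF3R in 5. HBB, HBD, ALAS2, IL7R, IGKC, JCHAIN, MNDA and CSF3R were named after their values were seen. Platelet genes had a median of 0 and a highest sum of 14.4 CPM, with any count in 8 libraries and ITGA2B counted in 4. No count was found in any library for TRAC, MMP9, LCN2, AHSP, PF4, PPBP, GP9, TUBB1, PF4V1, KRT2, CA9, RPL10L or RPL3L. By counting error of single counts alone, a count of 0 allows up to 0.483 CPM (median over libraries). Small counts peaked at multiples of 3 and zeros were more frequent than under Poisson counting, so higher levels are not excluded. Keratinocyte genes, a check on skin cells, summed to 56.7 CPM (range 0 to 164). Of these DSP, which ependymal and other epithelia also use, had 50.2 CPM and KRT5 1.06 CPM, while KRT10 had a count in 20 libraries and KRT1 in 1.

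**Figure D2:**
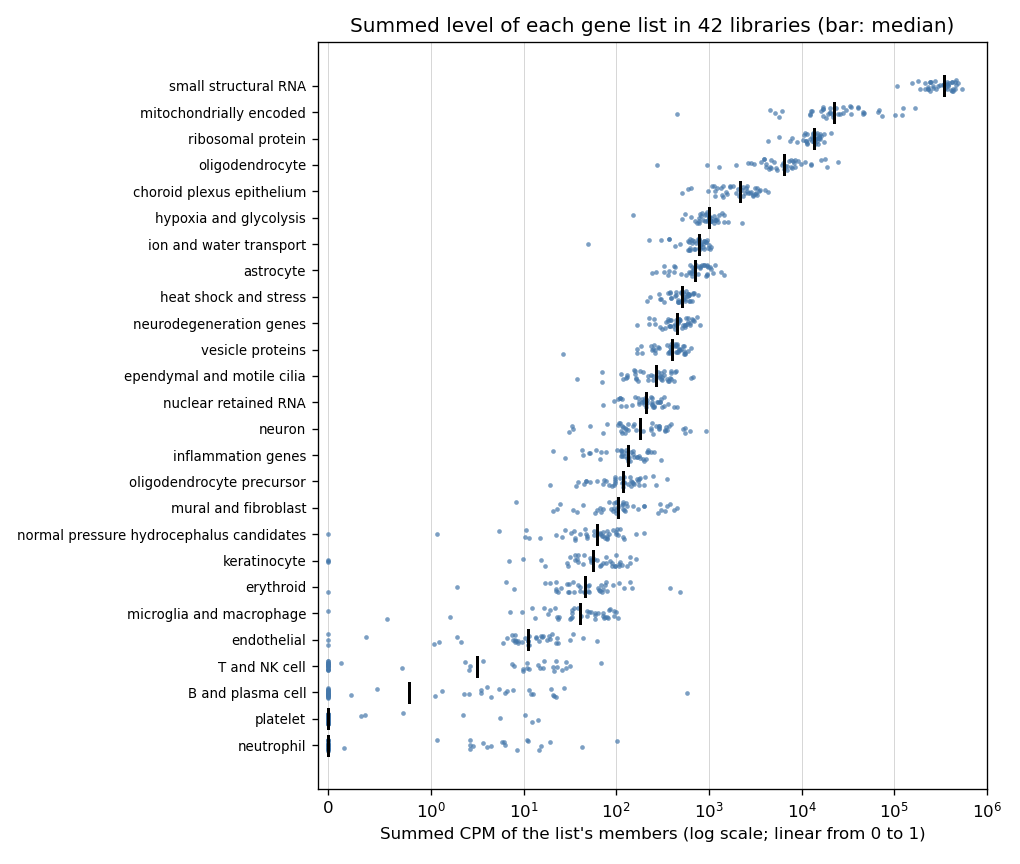
Summed CPM of the members of each of the 26 gene lists; each point is 1 of 42 libraries and the black bar is the median. The axis is logarithmic above 1 and linear from 0 to 1. Medians run from 0 for neutrophil and platelet genes over 2174 CPM for choroid plexus genes to 342349 CPM for small structural RNA.

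Among the other lists, small structural RNA summed to 342349 CPM (range 108044 to 545853), with RN7SK at 1441 CPM and RPPH1, the RNA of ribonuclease P, at 1326 CPM behind RN7SL1 and RN7SL2. The 13 mitochondrial mRNAs summed to 22483 CPM (range 456 to 167516), with MT-ND5 at 2669.8 CPM and MT-ND2 at 2069.9 CPM after MT-CO1 and MT-ND4. Ribosomal protein genes summed to 13598 CPM (range 4373 to 20770), with RPL3, RPL13A (354 CPM), RPL37A (352 CPM) and RPS6 (331 CPM) highest. Genes of hypoxia and glycolysis summed to 1002 CPM, with GAPDH at 304 CPM, ALDOA at 185 CPM, PKM at 169 CPM and ENO1 at 164 CPM. Ion and water transport genes, several of which serve CSF secretion, summed to 772 CPM, with the kinases WNK1 (216 CPM) and STK39 (91.6 CPM), carbonic anhydrase CA2 (203 CPM) and SLC4A2 (49.0 CPM). Heat shock and stress genes summed to 514 CPM, 71.1% of it HSP90AA1 (366 CPM), with HSPB1 (39.0 CPM), HSPH1 (25.7 CPM) and DNAJB1 (23.3 CPM) after it. Genes tied to neurodegeneration summed to 457 CPM, with SOD1 at 84.5 CPM, the amyloid precursor APP at 75.7 CPM, PICALM at 68.4 CPM and SQSTM1 at 46.4 CPM. Genes of proteins commonly found in vesicles summed to 396 CPM, with HSPA8 at 165 CPM, ANXA2 at 56.9 CPM, ANXA5 at 40.03 CPM and SDCBP at 32.0 CPM. Nuclear retained RNA summed to 209.8 CPM, with SNHG14 at 105 CPM, MALAT1 at 74.9 CPM, NEAT1 at 23.5 CPM and MEG3 at 2.105 CPM. Inflammation genes summed to 133 CPM, of which SOD2 was 78.0%; STAT3 had 11.1 CPM and IL18 1.16 CPM, and IL1B had a count in 4 libraries. Of the candidate genes of normal pressure hydrocephalus, the cilia gene CFAP43 had a median of 39.2 CPM and DNAH14 10.0 CPM, while SFMBT1 had a count in 19 libraries and CWH43 in 2; their sum was 61.8 CPM.

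Mitochondrial transcripts were the largest set among genes that varied more than others of like abundance. Of 7700 genes tested, 43 varied more than genes of like abundance at an adjusted p under 0.05 (edgeR quasi-likelihood, Benjamini-Hochberg), 256 at an unadjusted p under 0.05. They included 10 of 13 mitochondrial mRNAs, 5 of 21 mitochondrial tRNAs and 5 nuclear copies of mitochondrial genes. Adjusted over the list alone, 13 of the 13 mitochondrial mRNAs passed, and their F ratios lay between 3.24 and 5.24 (median 3.68). In absolute terms they varied less than the median gene, with a median SD of 1.53 in log2 CPM against 2.40 for all tested genes. MT-CO1 ran from 75.9 to 45049 CPM, MT-ATP6 from 0.997 to 6849 CPM (F = 5.24, adjusted p = 0.00337) and MT-ND6 from 14.2 to 9848 CPM (F = 4.59, adjusted p = 0.00953). The largest F ratio was that of the 7SL copy RN7SL3 (9.18, adjusted p = 1.50e-05), which ran from 0.465 to 19870 CPM, followed by the mitochondrial tRNAs MT-TL2 (8.46) and MT-TK (5.68) and by MTURN (5.38, from 0 to 6104 CPM). The others of the first 20 were DAAM2, the kinesin KIF5C, GMFB, DYNC2I1, the glutamate transporter SLC1A2, MT-TS2, MT-CYB, AIFM3, CBX5, RTN4, MTND1P23, MT-ND5, the oligodendrocyte gene BCAS1 and MT-ND4L, with F ratios from 3.90 to 5.21. KIF5C, SLC1A2 and AIFM3 each had a count in 25 of 42 libraries. With total counts only in place of TMM, 31 genes passed, 25 of them shared, and KIF5C, SLC1A2, CBX5 and MT-ND4L did not. With at least 10 counts in all libraries, 0 of 297 genes passed, and MT-CO1 and MT-ND5 were among those tested.

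Of the cell type lists, the astrocyte gene SLC1A2, the oligodendrocyte gene MOBP and the mural cell gene RGS5 passed over all genes, as did CA2 of the transport list. Adjusted over the list alone, 1 of 15 choroid plexus genes, 2 of 11 oligodendrocyte genes, 3 of 6 mural and fibroblast genes, 2 of 10 hypoxia and glycolysis genes and 1 of 5 erythroid genes passed, and 0 of 12 neuron genes and 0 of 11 ependymal genes, with 3 and 2 at an unadjusted p under 0.05 by edgeR. No ribosomal protein gene passed (1 of 79 at an unadjusted p under 0.05): their median F ratio was 0.606, with a median SD of 0.76 in log2 CPM. Among the smallest F ratios were those of EEF1A1P19, RN7SL128P, RNU6-6P and RNU6-33P. On simulated counts 48 of 100 genes with a 3-fold raised dispersion were called.

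**Figure D3:**
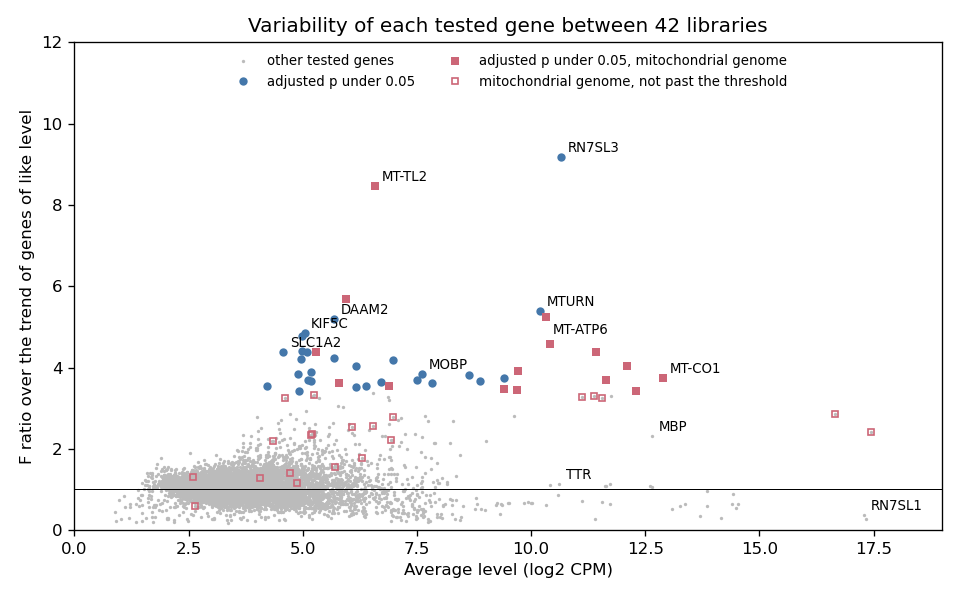
F ratio of each tested gene's variability over the trend of genes of like level, against the average log2 CPM; each point is 1 gene over 42 libraries and the line marks a ratio of 1. Filled points pass the adjusted threshold of 0.05, and squares are genes of the mitochondrial genome. RN7SL3 has the highest ratio, 9.18, and TTR, at 1.14, lies near the line.

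Members of 7 of the 9 cell type lists that could be scored rose and fell together across libraries. Of 18 scored lists, 10 had a higher mean correlation between members than matched random lists (one-sided, adjusted p between 0.000300 and 0.0131). Mitochondrial mRNAs had a mean rho of 0.922 against 0.192 for random lists, and small structural RNA had 0.580 against 0.163. Oligodendrocyte genes had 0.397, neuron genes 0.356, choroid plexus genes 0.342, ribosomal protein genes 0.337, microglia genes 0.302, ependymal genes 0.284, astrocyte genes 0.265 and oligodendrocyte precursor genes 0.237, with medians of random lists between 0.0982 and 0.150. Erythroid (0.107), mural and fibroblast (0.173), vesicle protein (0.0809), neurodegeneration (0.164), ion and water transport (0.196), nuclear retained RNA (0.164), hypoxia and glycolysis (0.115) and heat shock genes (0.194) did not pass. With total counts only, the astrocyte value was 0.0566 (adjusted p = 0.856), and the precursor, microglia and small structural RNA lists did not pass either, while ion and water transport, hypoxia and glycolysis and heat shock genes did.

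Scores of the ventricle's lining and of the brain tissue around it correlated less with each other than within each set; the sets were formed after these correlations were seen. Choroid plexus and ependymal scores rose together (rho = 0.724, r = 0.853, both permutation p = 1e-05, adjusted p of rho = 0.000153; r = 0.801 without 2 libraries; rho = 0.756 in the 37 libraries). Astrocyte and oligodendrocyte precursor scores did so too (rho = 0.867, r = 0.850, both p = 1e-05, adjusted p of rho = 0.000153; r = 0.833 without 2 libraries; rho = 0.873 in the 37 libraries). The value of rho was 0.742 for oligodendrocytes and their precursors, 0.6997 for astrocytes and oligodendrocytes, 0.7003 for precursors and microglia, 0.667 for neurons and astrocytes, 0.606 for astrocytes and microglia, 0.496 for neurons and precursors, 0.440 (r = 0.487) for oligodendrocytes and microglia, 0.425 for neurons and oligodendrocytes and 0.361 for neurons and microglia, each with an adjusted p of 0.0432 or less. With depth and detected genes regressed out, neurons with oligodendrocytes (0.240), precursors (0.228) and microglia (0.0803), and microglia with oligodendrocytes (0.197) and astrocytes (0.370, adjusted p = 0.0557), no longer passed. Random pairs of lists also correlate: of the 11 pairs within the sets, 3 lay above nearly all random pairs and 3 under the random median, namely neurons with oligodendrocytes (7.4th percentile, random median 0.581), microglia (14.6th) and precursors (19.9th). Between these sets rho was lower: over the 10 pairs it ran from 0.0103 to 0.393, the highest being ependymal and microglia genes (r = 0.405, adjusted p of rho = 0.0265), the only pair past the threshold by rho, while 5 of the 10 passed by r. With depth and detected genes regressed out, that pair turned to -0.0490 and did not pass, while 6 of the other pairs became negative past the threshold: choroid plexus with neuron (-0.440), oligodendrocyte (-0.459) and astrocyte genes (-0.408), and ependymal with neuron (-0.495), oligodendrocyte (-0.481) and astrocyte genes (-0.457). As measured, rho was 0.337 for ependymal and precursor genes (r = 0.502, adjusted p of rho = 0.0578, of r = 0.00193), 0.274 for choroid plexus and precursor genes (r = 0.473, adjusted p of r = 0.00341), 0.245 for ependymal and astrocyte genes (r = 0.374, 0.0227), 0.225 for choroid plexus and microglia genes and 0.183 for choroid plexus and astrocyte genes (r = 0.330, 0.0453). It was 0.0103 for choroid plexus and neuron genes (adjusted p = 0.967), 0.0109 for choroid plexus and oligodendrocyte genes, 0.0387 for ependymal and neuron genes, and 0.125 for ependymal and oligodendrocyte genes. All 10 lay under the random median, and random pairs matched to these last 4 had median rho values between 0.580 and 0.635, with none of 1000 as low. The random lists were matched on abundance only, and their members correlated less with each other. They cannot tell whether other lists with such correlated members would lie as low.

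Mitochondrial mRNAs correlated with 4 of the 5 brain tissue lists, none beyond the range of random pairs: rho was 0.6098 with the neuron score (r = 0.665; adjusted p of rho = 0.000478; rho = 0.661 in the 37 libraries; 88.9th percentile of random pairs), 0.583 with the astrocyte score (67.5th), 0.534 with the precursor score (80.0th) and 0.494 with the oligodendrocyte score (37.7th). It was 0.272 with the microglia score (adjusted p = 0.132). With the choroid plexus and ependymal scores it was -0.231 (r = -0.184, adjusted p of rho = 0.210) and -0.185 (adjusted p = 0.313), below all 1000 random pairs of each. Members of those random lists correlated less with each other, so lists with correlated members may fall below them more easily. With depth and detected genes regressed out, the precursor pair (rho = 0.221) no longer passed, and the choroid plexus and ependymal pairs became negative past the threshold (-0.638 and -0.682, both adjusted p = 0.000918). The joint score of the 2 lining lists and that of the 5 brain tissue lists had a rho of 0.1297 (r = 0.323, permutation p = 0.410 and 0.0368, adjusted p of rho = 0.410 over 6 relations; r = 0.172 without 2 libraries; rho = 0.203 in the 37 libraries). With total count and detected genes regressed out, rho was -0.509 (r = -0.528, p = 0.000720 and 0.000250, adjusted p of rho = 0.00108; r = -0.516 without 2 libraries; rho = -0.531 in the 37 libraries).

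Over all 153 pairs of scored lists, 75 correlated positively past the threshold and 0 negatively, with 0 negative pairs at an unadjusted p under 0.05; by Pearson's r, 110 passed, all positive. With total counts only, 48 were positive and 6 negative; with depth and detected genes regressed out, 26 and 14; without the 4 shallowest libraries, 42 and 0. The median rho of pairs was 0.341 against 0.524 for random pairs, so passing the threshold does not set a pair apart from random pairs. Of the pairs, 56 lay under the 2.5th percentile of their random pairs and 4 in the upper tail of the same size. The 3.83 expected in each tail assume lists like the random ones. Those were matched on abundance only, and their members correlated less than those of the 10 coherent lists. The 56 are therefore not read against chance. The choroid plexus and ependymal pair, at the 88.3rd percentile, was within the range of random pairs. The 75 positive pairs all had a rho above 0 in the 37 libraries.

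**Figure D4:**
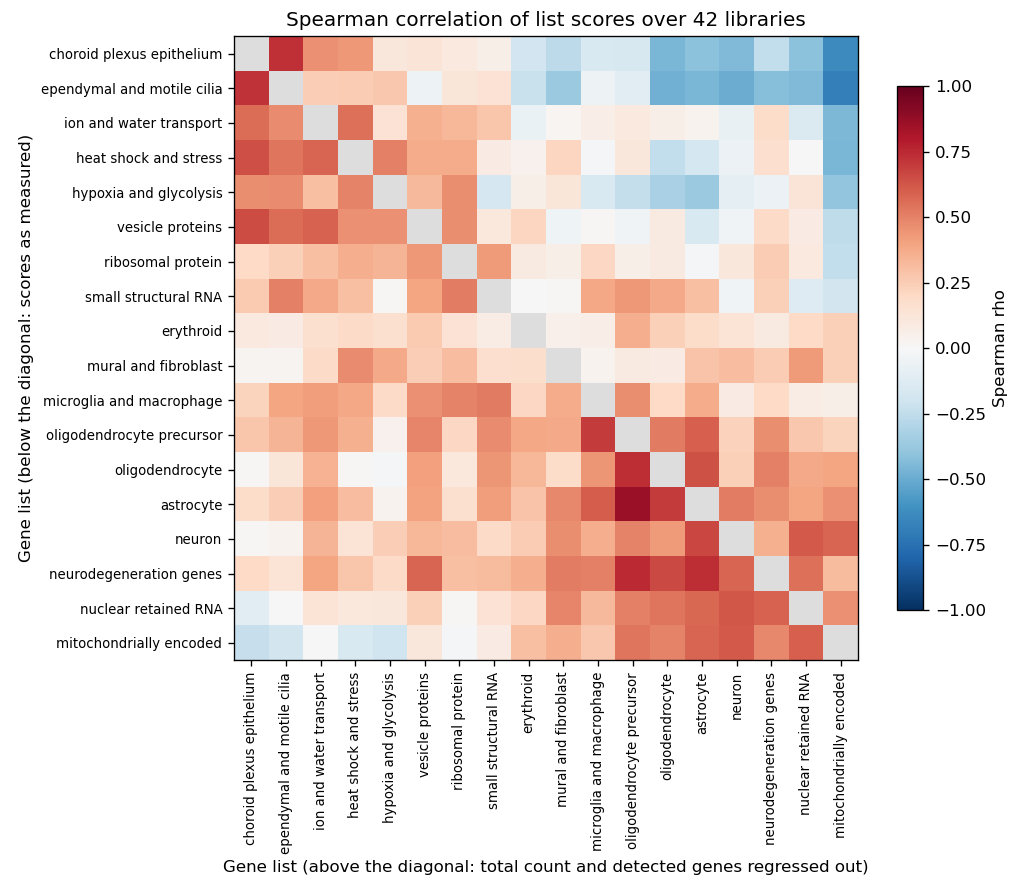
Spearman rho between the scores of 18 gene lists over 42 libraries. Below the diagonal the scores are as measured, and above it the total count and the number of detected genes are regressed out; red is positive, blue negative and grey the diagonal. Choroid plexus and ependymal genes reach 0.724 with each other and, as measured, 0.0103 and 0.0387 with neuron genes.

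List scores followed library depth, a relation that was not set against random lists. Of 36 relations of 18 scores with log10 total count and detected genes, 28 were positive past the threshold and 0 negative (13 with total counts only), and all 28 were above 0 in the 37 libraries. The vesicle protein score followed the number of detected genes most closely (rho = 0.784, r = 0.810, both p = 1e-05, adjusted p of rho = 0.000120, r = 0.765 without 2 libraries). The ependymal score followed the total count (rho = 0.666, r = 0.723, both p = 1e-05, r = 0.664 without 2 libraries). Total count was not followed past the threshold by ribosomal protein genes (rho = 0.147, adjusted p = 0.351), erythroid genes (rho = 0.198, adjusted p = 0.214), mural and fibroblast genes (rho = 0.227, adjusted p = 0.155) or hypoxia and glycolysis genes (rho = 0.287, adjusted p = 0.0724). Of these the erythroid, mural and hypoxia scores followed detected genes (rho = 0.382, 0.439 and 0.516).

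The first principal component held 21.7% of the variance (jackknife SE 4.06) and followed the number of detected genes (rho = 0.954, r = 0.942, both p = 1e-05; r = 0.923 without 2 libraries; rho = 0.956 in the 37 libraries). Its largest positive loadings were those of ATXN10, TWF1, CA2, EPS15, UQCRC2, GTF2IP4, BAG1, ADI1 and KDM5A, and its negative loadings, all smaller in size, those of BCAS1, RN7SL3, H2AZ1, NSUN3, TGIF1, AHNAK, SLC37A3, FRY, HELLPAR and NEB. The second component held 4.48% and did not follow detected genes past the threshold (rho = -0.0346, p = 0.829). It set neuron, oligodendrocyte and mitochondrial genes (each above all 10000 random lists) and genes of precursors, neurodegeneration and astrocytes (99.9th, 99.8th and 99.7th percentile) at its positive end, against choroid plexus (below all 10000) and ependymal genes (0.03rd percentile) at its negative end, with adjusted p of 0.0408 or less. Members of these lists correlated more with each other than the median of random lists, so extreme median loadings come more easily to them. The percentiles and p of component 2 can thus overstate the difference. The positive loadings of component 2 were led by PHACTR3, ALDOC, SILC1, MAP7, TUBB2B, RPH3A, RHOU, PLEKHA6 and RAPGEF4, and its negative ones by LIMK2, AIFM3, ZNF460, GSTM4, RPRD1B, BCAT2, CTBP2, BUB1B and the cilia genes IFT122 and MORN2. The third component held 4.12%. The 3 libraries farthest out made up 48.2%, 42.1% and 62.5% of the squared scores of components 1, 2 and 3.

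**Figure D5:**
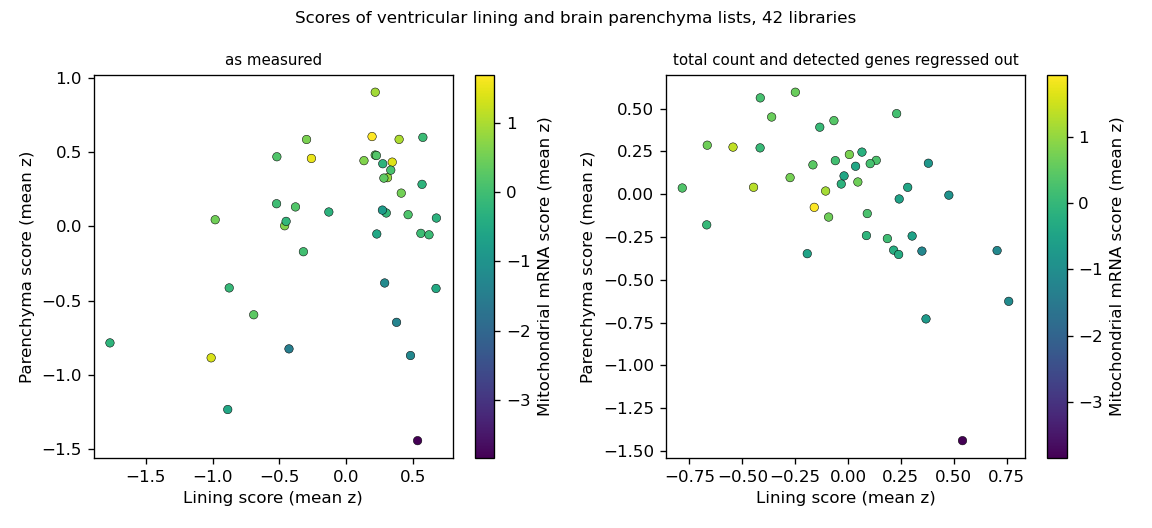
Mean z-score of the choroid plexus and ependymal lists (lining, x axis) against that of the neuron, astrocyte, oligodendrocyte, precursor and microglia lists (parenchyma, y axis); each point is 1 of 42 libraries, coloured by the mean z-score of mitochondrial mRNAs. Left, as measured, rho is 0.1297; right, with total count and detected genes regressed out, rho is -0.509.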

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

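The row of the table that names no gene stands apart because it holds counts outside the named genes that every value above rests on. It took a median of 76.5% of all counts of a library (range 52.8% to 83.4%), so that named genes rest on the smaller part of the counts. What it contains was not analysed here.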

How the results depend on the processing

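Of 550 repeated values, 98 concerned the main counts and levels and 85 of these kept their side. The count of variable genes rose from 43 to 273 with no filter on low counts (24730 genes tested) and to 145 with DESeq2's dispersion outliers, of which 41 were shared. With at least 10 counts in all libraries it was 0 of 297 genes by edgeR, with 22 at an unadjusted p under 0.05 and 16 by DESeq2; fewer genes were tested and the trend rested on them. Positive pairs of lists fell from 75 to 48 with total counts only, to 26 with total count and detected genes regressed out and to 42 without the 4 shallowest libraries. Negative pairs rose from 0 to 6 with total counts only and to 14 with depth regressed out. Depth relations fell from 28 to 13 with total counts only. With depth and detected genes regressed out, the 14 negative pairs included 6 of lining with brain tissue lists whose rho was above 0 but did not pass as measured: choroid plexus with oligodendrocyte (rho = -0.459), neuron (-0.440) and astrocyte (-0.408), and ependymal with oligodendrocyte (-0.481), neuron (-0.495) and astrocyte (-0.457). Ependymal and microglia turned to -0.0490 and no longer passed. Regression can itself push lists apart. Among single genes, lists and pairs, 398 kept their side, 33 no longer passed, 14 newly passed and 7 turned direction. With the first dispersion method, genes following the lining score went from 6 to 44 (rose) and from 9 to 27 (fell), and those following the parenchyma score from 15 to 117 and from 0 to 4; the method was changed after these were seen. The runs without the 5 deepest libraries, without the library of highest neuron level and without near-identical copies were chosen after seeing the data, and none of their main counts moved by over 1.5 times. No paired analysis was possible because the labels give 1 group. At this depth, a gene at 0 in the shallowest library is limited only to 1.92 CPM.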

Other observations

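Tests chosen only after their result was seen are the share of zeros at high expected counts, the relation of mitochondrial and parenchyma scores, and the median of cilia genes as a set; the lining and parenchyma sets of lists, the run without the 5 deepest libraries, the random sets split at their best and thinning in units of 3 counts were also chosen after the data were examined, as was the dispersion method of the fit on the lining and parenchyma scores. The labels give 1 group, so no biological explanation by group was tested.

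Few genes outside the cell type lists followed the lining or parenchyma score past the threshold. An edgeR quasi-likelihood model held the lining score, the parenchyma score, detected genes and log10 total count. All 7700 genes were fitted and adjusted together (Benjamini-Hochberg). The adjustment thus included the genes that make up the scores, which can ease the threshold for the others. Of the 7629 genes outside the lists of the 2 scores, 15 rose with the parenchyma score and 0 fell (420 and 17 at an unadjusted p under 0.05). SCD, a fatty acid desaturase, rose by 1.503 on the log2 scale per SD of the score (SE 0.28, adjusted p = 0.00274), and TUBB4A by 2.03, the astrocyte genes FAM107A and SPARCL1 by 0.94 and 2.11, the neuronal kinase CAMK2A by 2.83 and KIF5C by 4.25. ASPA, PADI2, PMP2 and the mitochondrial rRNAs MT-RNR1 and MT-RNR2 also rose. With the lining score, 6 genes rose and 9 fell (493 and 103 at an unadjusted p under 0.05): AIFM3 rose by 6.25 (SE 0.78, adjusted p = 4.59e-07), SMIM3 by 4.27, ZBTB43 by 3.48, the glucose transporter SLC2A12 by 3.24, RBM47 by 1.68 and ezrin (EZR) by 0.83. The 9 that fell were mitochondrial, among them MT-ND2 (-1.42) and MT-ND6 (-1.70). These genes were named after their values were seen. AIFM3 (median 3.39 CPM) and KIF5C (5.28 CPM) each had a count in 25 of 42 libraries, and SMIM3 had a median of 4.20 CPM. Their slopes rest in part on zeros and low counts and are not taken as sizes of change. A first fit, with edgeR's current dispersion method, had called 44 genes that rose and 27 that fell with the lining score, and 117 and 4 with the parenchyma score. The method was changed after these counts were seen, because that fit called 16 of 7500 unchanged genes on simulated counts; the fit used here called 0, but found only 4 of 100 genes given 1 log2 unit per SD and 7 of 100 given 1.5.

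A hypothesis, written before its test, was that cilia genes outside the ependymal list follow the lining score. Of 45 tested genes named DNAH, DNAI, CFAP, IFT, RSPH, SPAG or TEKT, 0 passed the test (11 rose at an unadjusted p under 0.05), an odds ratio of 0 (Fisher's exact p = 1); 6 other genes passed, so that 0.0354 were expected by chance. The prediction, an odds ratio over 2, failed as written, and the value met the bound set for its failure. With under 1 cilia gene expected the test was nearly bound to end at 0, so it is read as undecided, a reading chosen after the value was seen. The first fit also gave 0 of 45, with 0.260 expected. A test of the set was then added. As a set they leaned towards the lining score: 42 of 45 had a positive slope, with a median of 0.83 on the log2 scale per SD against 0.24 for random sets of like abundance, and 0 of 10000 random sets reached it. The lining score itself holds cilia genes, so the set was fitted again on the choroid plexus score alone, which holds none, with the prediction written before: the median was 0.60 against 0.17 for random sets, 40 of 45 were positive, and 0 of 10000 random sets reached it. The choroid plexus and ependymal scores were already seen to correlate (rho = 0.733 with depth and detected genes regressed out). Genes leaning towards 1 score were thus likely to lean towards the other, and the second fit is no independent check. Genes of a set are not independent replicates, and the random sets were matched on abundance only. Ciliary transcripts may rise and fall with those of the choroid plexus, as a hypothesis found and tested on the same libraries.

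A first pattern is that genes were often at 0 in some libraries beside high counts in others. Where at least 20 counts were expected from the gene's mean, 19.8% of gene and library pairs were at 0, against 1.45e-09% under Poisson counting. Too shallow sequencing is argued against: thinning each library to 0.5 of its counts removed a median of 1.19% of its detected genes, and 3.06% in units of 3 counts, at which small counts peak. Few starting RNA molecules, amplified many times, could give such zeros, and so could differences between patients; these cannot be told apart here, since each patient has 1 library.

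A second pattern is that lining and parenchyma lists correlated less with each other than within each set. As measured, rho between the sets was above 0 throughout (0.0103 to 0.393). The joint scores ran against each other only with depth and detected genes regressed out. The mean rho was 0.612 within the sets (11 pairs) and 0.184 between them (10 pairs), a gap of 0.427 (jackknife SE 0.148). This gap restates the correlations the sets were formed from. With each of 1000 random sets split at its best, 0 reached it among splits into 2 and 5 lists (highest 0.307) and 6 among all splits in 2. The random lists were matched on abundance, and their members correlated less with each other (medians from 0.0982 to 0.117) than those of the lists used (0.237 to 0.397). They cannot tell whether other lists with such correlated members would split as far. Regressing out depth and detection did not remove the gap, which was then 0.739 (SE 0.178), against at most 0.718 in random sets treated alike and split at their best. Mean rho fell to 0.417 within the sets and to -0.322 between them. The lists of both sets followed depth in the same direction, and regression can itself push lists apart. This therefore cannot decide on depth and detection as the cause. Scaling is argued against by gaps of 0.433 (SE 0.152) with DESeq2 size factors and 0.459 with total counts only, and the 5 deepest libraries by a gap of 0.371 (SE 0.157) without them. The patients may differ in how much vesicle RNA comes from the ventricular lining and how much from brain tissue, as a hypothesis. Depth and detection stay open, as do differences in how fluid was collected, on which no label bears.

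Another pattern is that mitochondrial mRNAs varied more than genes of like abundance. It depended on the genes tested: with at least 10 counts in all libraries, 0 of 297 genes passed by edgeR. MT-CO1, MT-ND2, MT-ND4 and MT-ND5, at 42.1 CPM or more in every library, were among the 297, and the trend then rested on those few genes. Scaling is argued against, since the median F ratio of the mitochondrial mRNAs was 3.51 at the lowest with total counts only or DESeq2 size factors. For the 5 nuclear copies of mitochondrial genes, reads shared with the parent could not be decided: the median rho with the parent was 0.737, from 0.492 for MTRNR2L8 to 0.967 for MTCO1P12. With depth and detected genes regressed out, the mitochondrial score followed the parenchyma score (rho = 0.529, r = 0.676, permutation p = 0.00049 and 7.0e-05, adjusted p of rho = 0.00098 over 6 relations; r = 0.538 without 2 libraries; rho = 0.502 in the 37 libraries) and ran against the lining score (rho = -0.734, r = -0.647, both p = 1e-05; r = -0.709 without 2 libraries; rho = -0.764 in the 37 libraries). As measured, rho was 0.620 with the parenchyma score and -0.237 with the lining score (adjusted p = 0.157), so the negative relation passes only after a regression that can itself push scores apart. More material of parenchymal cells stays a candidate explanation; damaged cells or free mitochondria in the fluid were not tested.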
